A study of Escherichia coli with 20 samples.

How the data were processed

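RNA of Escherichia coli, of the culture collection reference strain that the labels name, was measured by RNA sequencing in 20 libraries. Per the labels, overnight cultures in tryptic soy broth were resuspended, given 200 µL of water or of 0.5 µM SAPYR for 5 min in the dark, and then illuminated or held in the dark for 10 min. Total RNA was treated with DNase, depleted of rRNA with a stranded kit and sequenced on an Illumina NextSeq instrument, per the labels' protocols. The deposited table holds whole-number read counts per gene, read here as the authors' raw counts because their totals differ between libraries. The submitters' processing notes name FastQC, Trim Galore 0.6.4, STAR 2.6.1, featureCounts 1.6.4, MultiQC 1.7, R 3.5.1 and DESeq2 1.22. Which step each was used for is not given in the sources used here. The genome build and the strand setting of the counting are not given in the sources used here.

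Of the 3804 rows, 3723 carry identifiers of the ECDH10B form and 81 of the EBG form. These are identifiers of a K-12 type annotation, whereas the labels name another strain, so genes that differ in sequence between the strains can be undercounted and genes of the studied strain alone are not analysed here. Gene symbols are those of the deposited table. They were matched to the names in the RefSeq table of E. coli K-12 MG1655, used for names only: 3210 rows matched a current symbol, 485 an older one and 109 none. Because the builds were not stated to be the same, no coordinates are printed. There are 15 names that occur on more than 1 row of the deposited table, and genes with such a name were not named, since reads of near-identical copies can be lost or split. Without a stated strand setting, overlapping genes on opposite strands also cannot be told apart. No row is annotated as rRNA, and 24 rows are tRNA genes.

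Libraries were grouped by their labels into untreated in the dark, light alone, SAPYR in the dark, and SAPYR with light (called photodynamic), with 5 in each group. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Total counts ran from 6841273 to 12392953 per library. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 12.7, so none was counted as a repeat deposit.

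Genes with low counts were removed with filterByExpr, which left 3457 of 3804. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, in 1 quasi-likelihood model over all 20 libraries with group as the term. The robust quasi-likelihood F test was applied to 5 pairwise comparisons and to the interaction of SAPYR and light. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are given as log2 values with the standard error, and levels as CPM, counts scaled to a common library size, with TMM factors. Log2 CPM used a prior count of 2. Each library's total sets the precision of these levels, and low levels rest on few reads.

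The 48 gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took genes with a mean of at least 10 CPM in the compared groups, an adjusted p under 0.05 and no overlap between the groups' libraries. Of these, the 12 with the largest rise and the 12 with the largest fall were taken for photodynamic against untreated cells, and 5 each way for the other comparisons and, without the overlap condition, the interaction. Up to 4 called members per described list, or up to 2 members of a list with none called, and a set of 29 stress genes, of which 25 were tested, completed the rule. tRNA and rRNA genes were not named. The other 4 are not analysed here.

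The steps were tested on simulated counts for 3457 genes, drawn from the untreated libraries' means and all libraries' sizes, with 200 genes changed in each of 3 runs. A further 20 genes were changed together by 1.5-fold as a list. Camera gave that list an unadjusted p under 0.05 in 3 of 3 runs of each comparison, whereas list calls in the data are adjusted over the lists. For photodynamic against untreated cells, edgeR recovered 95.5% of the genes changed 4-fold, 72.1% of those changed 2-fold and 34.3% of those changed 1.5-fold, and 4.75% of its calls were false. For SAPYR in the dark, it recovered 98.5%, 80.1% and 29.4%, with 3.56% false calls. DESeq2 made 10.0% and 7.01% false calls in the same simulations. Genes were drawn independently, with 1 value of the spread per gene shared by all groups. A change of most genes, correlation within lists and libraries that stand apart within a group were not simulated. These rates and the camera result therefore need not hold for the real comparisons.

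The alternatives were DESeq2 1.42.0, RLE factors, library totals alone, no low-count filter, only the groups compared, a replicate block, a 2-fold minimum, removal of tRNA genes and the omission of each library in turn. For the lists they were an estimated correlation, fry, the block and the omission of libraries. A pair of further settings, without photodynamic libraries 2 and 5 and without 4 libraries that stand apart, were chosen after seeing the data.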

Results

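The study asked how E. coli responds to a sublethal photodynamic treatment, in which a photosensitizer, a compound that absorbs light and passes the energy on to form reactive oxygen species, acts together with light. SAPYR, a phenalene-1-one photosensitizer, was given at 0.5 µM or replaced by water, and the cells were then illuminated for 10 min or held in the dark for 10 min. This makes 4 groups of 5 libraries: untreated in the dark, light alone, SAPYR in the dark, and SAPYR with light (photodynamic). Total counts were 9079490 to 11359634 in untreated libraries and 6914641 to 10378098 with light alone. They were 6841273 to 8236316 with SAPYR in the dark and 8839143 to 12392953 in photodynamic libraries.

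On the first principal component of log2 CPM, with 67.7% of the variance, the 5 photodynamic libraries lay between 57.82 and 79.31 and the other 15 between -24.01 and -15.53. The second, with 12.9%, ran from untreated libraries to those with SAPYR in the dark, with light alone mostly between them. Libraries of the same group correlated at a Pearson r of at least 0.973 in untreated cells, 0.98 with light alone and 0.981 with SAPYR in the dark, but down to 0.877 among photodynamic libraries. Photodynamic replicates 2 and 5 lay apart from the rest of their group, at 18.46 and -20.03 on the second component, where the other 3 lay between 0.81 and 3.61.

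**Figure D1:**
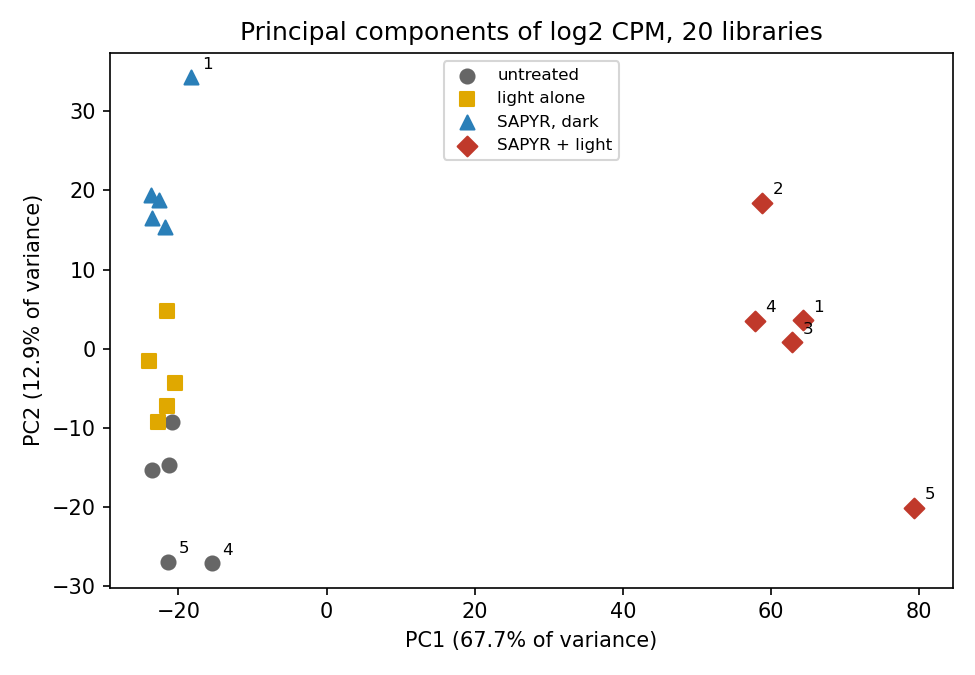
First and second principal components of log2 CPM (arbitrary units, share of variance on each axis) for 20 libraries, with 1 point per library, colour and shape for the group, and replicate numbers beside photodynamic libraries and others far from 0 on the second component. The photodynamic libraries lie between 57.82 and 79.31 on the first component, and all others lie below 0.

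Photodynamic treatment raised all 21 tested heat shock genes and lowered all 14 tested acid resistance genes, compared with untreated cells (camera adjusted p = 0.075 and 0.17 with an estimated correlation). With library totals alone 12 acid resistance genes fell. SAPYR in the dark also lowered 12 of these 14 genes, so most of their fall was present without light. The largest rise was in cpxP (ECDH10B_4103), a periplasmic protein of the Cpx envelope stress response, from 34.3 ± 8.91 CPM (SD, n = 5) in untreated cells to 4454 ± 2480 CPM. The periplasmic chaperone gene spy (ECDH10B_1881) rose 70.5-fold and ibpB (ECDH10B_3872), which encodes a small heat shock protein that binds aggregates, rose 50.2-fold. The acid chaperone genes hdeA and hdeB fell 83.3-fold and 87.5-fold, where leaving out photodynamic replicate 5 moved hdeB from a log2 fold change of -6.45 to -7.22. The formate hydrogenlyase gene hycB (ECDH10B_2892) fell from 657 ± 66.9 to 11.6 ± 4.94 CPM. In total 2589 of 3457 genes (74.9%) changed, 1496 up and 1093 down (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and of these 1034 rose and 624 fell by at least 2-fold.

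The 12 largest rises against untreated cells ran from a log2 fold change of 7.02 ± 0.38 (SE) for cpxP to 4.62 ± 0.28 for lpxP, which encodes a lipid A acyltransferase. Between them were spy (6.14 ± 0.32), ibpB (5.65 ± 0.28), the cation antiporter gene chaA (5.35 ± 0.23), ldrA (5.17 ± 0.51), the membrane protease gene htpX (5.05 ± 0.17), alx (4.97 ± 0.57), the arginine-binding protein gene artJ (4.81 ± 0.33), the sodium-proton antiporter gene nhaA (4.77 ± 0.33), nrdI (4.64 ± 0.42) and yjbO (4.63 ± 0.31), now called pspG. The adjusted p of these 12 genes was at most 1.6e-07 (edgeR). The alx level was set by photodynamic replicate 2, at 9.83 log2 CPM against 6.65 to 6.82 in the other 4, and leaving it out gave a log2 fold change of 3.59. The 12 largest falls held hdeB (-6.45 ± 0.46, and -7.22 without photodynamic replicate 5), hdeA (-6.38 ± 0.41) and hdeD (-5.45 ± 0.48, and -6.38 without photodynamic replicate 5), with gadB (-4.74 ± 0.43), a glutamate decarboxylase gene. Formate hydrogenlyase and its formate dehydrogenase gave hycA (-6.15 ± 0.30), hycB (-5.82 ± 0.24), hydN (-5.30 ± 0.22), hycF (-5.12 ± 0.26), hycC (-5.09 ± 0.25), hycE (-4.96 ± 0.28) and fdhF (-4.86 ± 0.23). The alcohol dehydrogenase gene adhE fell from 17238 ± 5482 to 646 ± 283 CPM, a log2 fold change of -4.74 ± 0.35.

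**Figure D2:**
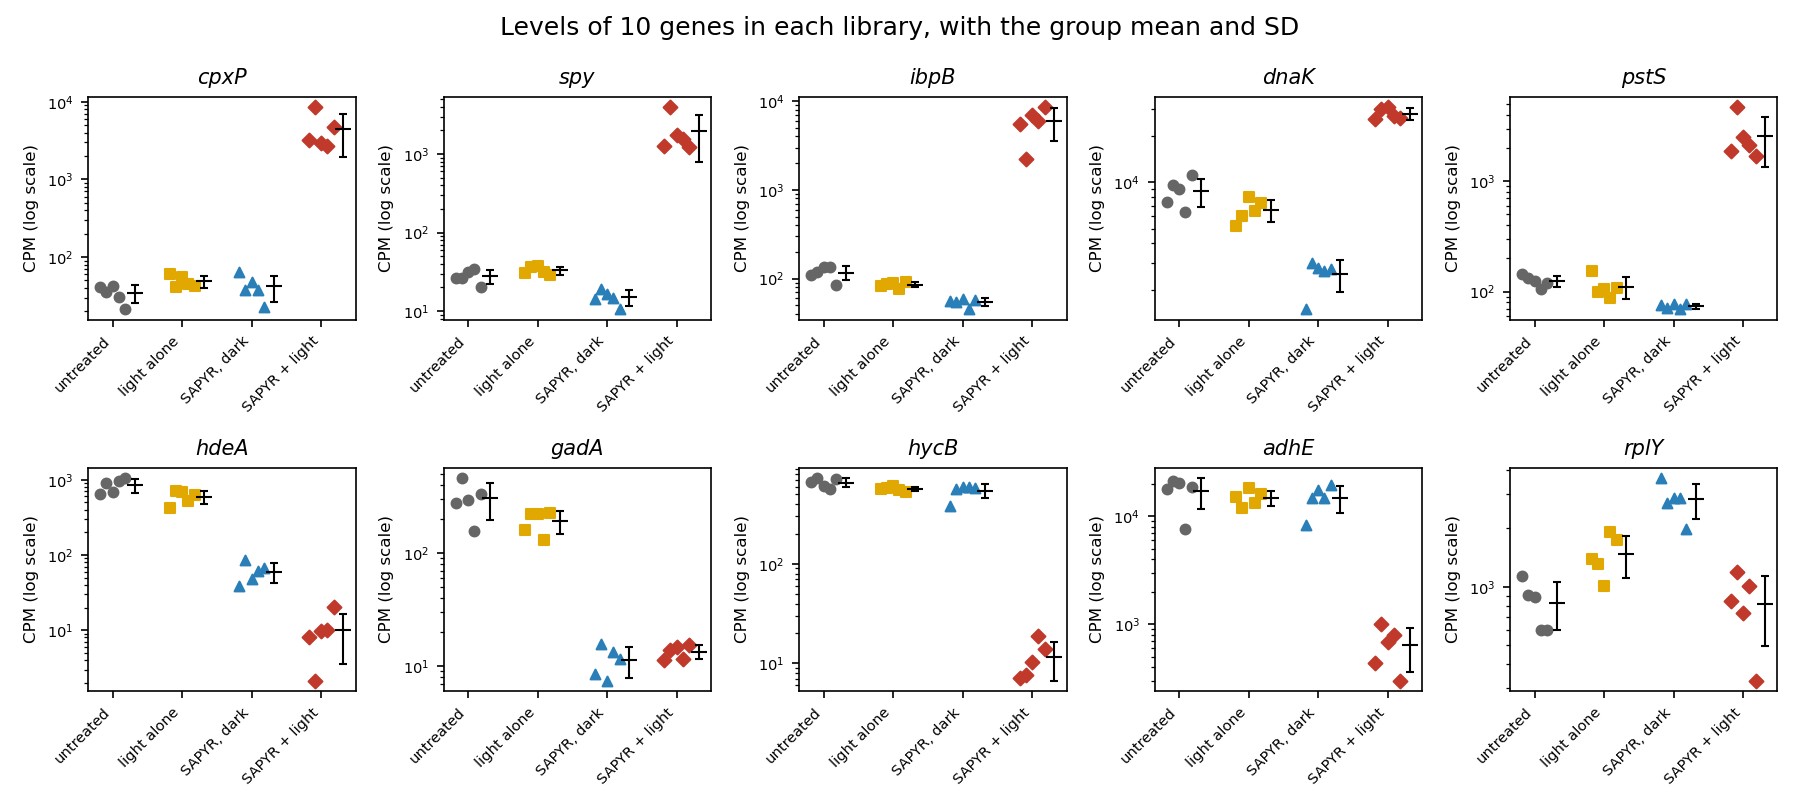
CPM on a log axis of 10 genes in each of the 20 libraries, grouped by treatment, with 1 point per library and the group mean and SD (n = 5) as a bar beside the points. For cpxP the photodynamic mean was 4454 CPM and no other group's mean was above 48.6, and gadA was at 11.3 CPM with SAPYR in the dark and 13.4 in photodynamic cells against 307 in untreated cells.

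All 21 tested heat shock genes rose in photodynamic cells, with a median log2 fold change of 1.68. Besides ibpB and htpX, hslR rose by 4.20 ± 0.20 and hslO by 4.11 ± 0.14 on the log2 scale, and dnaK, the main Hsp70 chaperone, went from 8749 ± 1831 to 28104 ± 2373 CPM. Of 12 Cpx genes 9 rose and 2 fell, with yebE at 4.39 ± 0.31 and yccA at 3.80 ± 0.12 beside cpxP and spy. Of 7 phage shock genes, which respond to damage of the inner membrane, 6 rose and 1 fell, and pspA was at 1476 ± 97.9 against 156 ± 20.1 CPM. The mean log2 CPM of the Cpx list was 9.95 in photodynamic replicate 2 against 9.03 to 9.24 in the other 4, and that of the phage shock list was 8.26 in replicate 5 against 7.53 to 7.69. With camera at the preset correlation the adjusted p was 2.1e-11 for heat shock, 3.3e-04 for Cpx and 3.3e-06 for phage shock. With an estimated correlation the adjusted p was 0.075, 0.28 and 0.11, so none of these list calls held. With fry it was 4.0e-12, 5.8e-09 and 7.3e-11, but fry does not compare a list with other genes and called 41 of 48 lists.

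Phosphate genes rose in 18 of 19 cases, led by pstS (4.37 ± 0.25), the periplasmic phosphate-binding protein, pstC (3.84 ± 0.18), pstA (3.72 ± 0.20) and phoR (3.63 ± 0.16), and 1 fell. Of 16 arginine synthesis and uptake genes 13 rose and 2 fell, with argC at 4.02 ± 0.22 and argB at 3.84 ± 0.19. The 2 that fell were carA (-2.27 ± 0.22) and carB (-2.42 ± 0.24), whose enzyme also feeds pyrimidine synthesis. All 16 genes of iron-sulphur cluster assembly rose, among them sufA (3.98 ± 0.25) and sufB (3.11 ± 0.17), and iscR was at 598 ± 105 against 104 ± 6.68 CPM. Of 43 listed iron uptake genes only 22 were tested, and 21 of these rose, with fhuF at 3.88 ± 0.34. Of 9 genes of fatty acid degradation 8 rose, with fadB at 3.57 ± 0.31. The camera calls at the preset correlation were lost for each of these lists, since the adjusted p with an estimated correlation was 0.075 for phosphate, 0.075 for arginine, 0.080 for iron-sulphur assembly, 0.32 for iron uptake and 0.15 for fatty acid degradation.

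Among the lists that camera called lower, all 14 tested acid resistance genes fell, with a median of -4.07. Of 17 glycolysis genes 15 fell and 1 rose, with tpiA at -3.17 ± 0.16, fbaA at -3.15 ± 0.20 and eno at -3.12 ± 0.24. Of 46 flagellar and chemotaxis genes 37 fell and 1 rose, with flgC at -4.47 ± 0.46. Purine synthesis had 12 of 14 genes lower, with purC at -3.07 ± 0.14, and pyrimidine synthesis 10 of 12, with pyrD at -3.13 ± 0.26. Of 10 porin and lipoprotein genes 8 fell, among them ompC (-2.98 ± 0.20) and lpp (-2.96 ± 0.23). Of 31 genes of anaerobic respiration 14 fell, 6 rose and 11 did not pass, with frdA of fumarate reductase at -3.93 ± 0.27. The adjusted p with an estimated correlation was 0.17 for acid resistance, 0.17 for glycolysis, 0.66 for flagella, 0.56 for purine, 0.28 for pyrimidine, 0.075 for porins and 0.66 for anaerobic respiration, so the camera calls of these lists at the preset correlation were lost as well. The last 5 called lists were pentose phosphate (7 of 10 down, pgl at -2.29 ± 0.17), thiol redox (10 of 14 down, 4 up, grxB at -2.20 ± 0.16), ATP synthase (8 of 9 down, atpG at -1.36 ± 0.21), NADH dehydrogenase (12 of 14 down, nuoM at -1.47 ± 0.27) and osmoprotection (11 of 14 up, osmY at 2.22 ± 0.23). Their adjusted p was 0.28, 0.28, 0.56, 0.66 and 0.28 with an estimated correlation, and with the preset correlation thiol redox was not called without photodynamic replicate 2 (0.086), and osmoprotection was not called in 2 of 10 fits with 1 library left out (up to 0.067, without photodynamic replicate 5). For the lists named here and in the preceding paragraphs on this comparison, the counts adjusted over the list alone equalled those over all genes.

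The lists of oxidative stress and DNA damage genes were not called, and their members went both ways. Of 8 tested OxyR genes 6 fell and 1 rose: dps, which encodes a DNA-binding ferritin-like protein, was at -3.12 ± 0.31, the catalase gene katG at -1.39 ± 0.27 and mntH, a manganese transporter, at 2.30 ± 0.17. Of 16 SoxRS genes 9 rose and 5 fell, with sodA at 1.89 ± 0.33. The regulator gene soxS had a mean of 167 CPM with an SD of 214 in photodynamic cells against 15.3 ± 2.14 in untreated cells, and marA, which activates multidrug resistance genes, 881 CPM with an SD of 1012 against 62.2 ± 14.9. The log2 fold change of soxS was 3.45 and 2.12 without photodynamic replicate 5, and that of marA was 3.82 and 2.73 without photodynamic replicate 2. Of 19 SOS genes, which respond to DNA damage, 11 rose and 2 fell (10 and 6 with RLE factors, 11 and 0 with library totals alone), with recX at 1.37 ± 0.18 and sulA at 1.05 ± 0.30, which was at 0.53 and no longer called without photodynamic replicate 5. The SOS repressor gene lexA, at 0.37 ± 0.14, was not called with DESeq2 (0.24), with RLE factors (0.25) or on leaving out untreated replicate 2, 4 or 5 (0.33, 0.30 and 0.24) or photodynamic replicate 2 (0.14). The camera adjusted p was 0.30 for OxyR, 0.78 for SoxRS and 0.46 for SOS. Of the other stress genes of the fixed set, fur (-0.03, edgeR adjusted p = 0.91) and nemA (-0.08, edgeR adjusted p = 0.66) did not pass. Counts adjusted over the list alone were the same for these 3 lists.

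The photodynamic libraries also differed in the spread of levels over all genes. Sorted by mean level into 10 bins, the lowest bin was higher than in untreated cells by a median of 1.5 on the log2 scale, and the ninth was lower by a median difference of -0.60. The top bin minus the bottom bin, as a median log2 difference from untreated cells, was -0.90 to -3.35 in the 5 photodynamic libraries, -0.57 to 0.18 in untreated, 0.04 to 0.43 in light-alone and 0.48 to 0.78 in SAPYR-dark libraries. With SAPYR in the dark the bottom bin was at a median of -0.28 and the top bin at 0.37, the opposite direction, and the cause was not tested. The lists raised by photodynamic treatment and those lowered by it moved in these same libraries. The median over all genes was 0.22 with TMM factors, 0.10 with RLE factors and 0.36 with library totals alone, and fold changes near these values depend on the scaling. The same 3 medians were -0.06, -0.05 and -0.25 for SAPYR in the dark, 0.13, 0.03 and 0.33 for photodynamic against light alone, 0.16, 0.03 and 0.50 against SAPYR in the dark, and 0.20, 0.10 and 0.61 for the interaction. Without the 4 libraries that stand apart (untreated 4, SAPYR in the dark 1, photodynamic 2 and 5, chosen after seeing the data), 2722 genes were called, of which 2414 were among the 2589.

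Light alone was compared with untreated cells to measure the effect of illumination without SAPYR. No gene passed the threshold in edgeR, where the lowest adjusted p was 0.14, while 558 of 3457 genes had an unadjusted p under 0.05 and DESeq2 called 26 genes, 6 up and 20 down. The stress genes that led the photodynamic comparison did not pass here: cpxP was at 48.6 ± 8.58 against 34.3 ± 8.91 CPM (log2 fold change 0.50 ± 0.30, edgeR adjusted p = 0.41), spy at 33.0 ± 3.80 against 27.9 ± 5.46 CPM, and dnaK at 6626 ± 1081 against 8749 ± 1831 CPM (-0.40 ± 0.19, edgeR adjusted p = 0.30). The blue-light receptor gene ycgF, now called bluF, had a log2 fold change of 0.17 ± 0.50 (edgeR adjusted p = 0.90), and phr, the photolyase gene phrB, one of 0.29 ± 0.12 (edgeR adjusted p = 0.23). Ribosomal protein genes had a median of 0.39, none of the 52 called, also when adjusted over the list alone, and acid resistance genes a median of -0.57, none of the 14 called, also when adjusted over the list alone. Histidine genes had a median of -0.41, with 6 of 8 lower when adjusted over the list alone and none over all genes. Cysteine and sulphate genes had the median furthest from 0, -1.56, with 4 of 17 lower when adjusted over the list alone and none over all genes. Their adjusted p was 0.62 with an estimated correlation, and 0.22 with the preset correlation without untreated replicate 4. Camera at the preset correlation called 15 lists, none of which was called with an estimated correlation or by fry. The adjusted p with an estimated correlation was 0.61 for ribosomal protein, acid resistance and histidine genes. The count of 0 genes rests on the libraries used and on the model: edgeR called 2 genes without light-alone replicate 3. Without the 4 libraries that stand apart, of which untreated replicate 4 belongs to this comparison, it called 268 genes, 79 up and 189 down. Leaving out untreated replicate 4 alone gave 0 genes, and so did a fit of only the groups compared. The 268 thus also rest on leaving out SAPYR libraries, which enter this comparison only through the shared fit. With the replicate number as a block edgeR called 46 genes, of which 71.7% rose.

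SAPYR in the dark lowered 12 of 14 acid resistance and 16 of 21 heat shock genes. It raised 42 of 52 ribosomal protein and 12 of 14 purine genes, compared with untreated cells. With an estimated correlation camera called acid resistance (adjusted p = 0.046), but not heat shock (adjusted p = 0.30), ribosomal protein (adjusted p = 0.60) or purine genes (adjusted p = 0.50). The glutamate decarboxylase gene gadA (ECDH10B_3694) fell 27.0-fold, from 307 ± 110 to 11.3 ± 3.42 CPM, and slp, an outer membrane lipoprotein gene, 29.8-fold. The chaperone gene dnaK fell 3.47-fold, to 2525 ± 595 CPM, and rplY (ECDH10B_2343), for ribosomal protein L25, rose 3.42-fold, from 825 ± 230 to 2820 ± 586 CPM. In all 1360 genes changed, 654 up and 706 down (edgeR, adjusted p under 0.05), of which 177 rose and 232 fell by at least 2-fold. With library totals alone the split was 404 up and 900 down, and without the low-count filter it was 463 up and 907 down, so the balance of directions depended on these choices. The share that rose was 48.1%, and 34.1%, 35.1% and 35.4% on leaving out untreated replicate 5, SAPYR-dark replicate 2 or SAPYR-dark replicate 4.

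The largest falls with SAPYR in the dark were gadB (-5.17 ± 0.46), slp (-4.90 ± 0.48), gadC (-4.76 ± 0.30), gadA (-4.75 ± 0.28) and hdeD (-4.37 ± 0.46). The largest rises were the serine deaminase gene sdaB (2.16 ± 0.39), ydgI (1.92 ± 0.33), the RNA helicase gene rhlE (1.80 ± 0.26), yjcD (1.77 ± 0.32) and rplY (1.77 ± 0.28). Of 14 acid resistance genes 12 fell and none rose, with a median of -3.91, and this was the 1 list of this comparison whose camera call held with an estimated correlation (adjusted p = 0.046). In SAPYR-dark replicate 1 gadB had no counts, so its -2.22 log2 CPM, against 0.843 to 1.42 in the other 4, is a floor set by the prior count. In the same library slp was at 0.730 against 3.09 to 3.58.

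Heat shock genes fell in 16 of 21 cases, with clpB at -2.03 ± 0.24, dnaK at -1.79 ± 0.19 and ibpA at -1.67 ± 0.24, and none rose (camera adjusted p = 2.6e-08, 0.30 with an estimated correlation). The list's mean was 8.65 log2 CPM in SAPYR-dark replicate 1 against 9.02 to 9.12 in the other 4. Ribosomal protein genes rose in 42 of 52 cases over all genes tested and 48 adjusted over the list alone, with rplY, rpsF (1.59 ± 0.25) and rpmC (1.49 ± 0.31) (adjusted p = 0.60 with an estimated correlation). Of 14 purine genes 12 rose, with purK at 1.63 ± 0.26 (adjusted p = 0.50 with an estimated correlation), and all 8 histidine genes fell, with hisC at -1.10 ± 0.18 (adjusted p = 0.50 with an estimated correlation). Of 7 ribosome hibernation genes 4 fell and 2 rose, with yfiA, now called raiA, at -3.15 ± 0.34, sra at -2.61 ± 0.40 and hpf at -1.85 ± 0.18 (adjusted p = 0.22 with an estimated correlation), and the count adjusted over the list alone was 5 down and 2 up. Of 22 genes of the general stress sigma factor RpoS 14 fell and 1 rose, or 14 and 2 adjusted over the list alone, with wrbA at -1.48 ± 0.17 (adjusted p = 0.38 with an estimated correlation). The cysteine and sulphate genes were not called as a list (camera adjusted p = 0.10), though 10 of 17 fell, 11 adjusted over the list alone, among them cysD (-3.07 ± 0.86, and -2.24 without untreated replicate 4). Adjusted over the list alone, the counts were the same for acid resistance, heat shock, purine and histidine genes.

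Camera at the preset correlation called 7 further lists with SAPYR in the dark. Of 12 fatty acid synthesis genes 8 rose, with fabA at 1.31 ± 0.19, and of 12 ribosome factor genes 7 rose, with rimM at 1.32 ± 0.23. Of 22 tested iron uptake genes 10 rose (11 adjusted over the list alone), with fecR at 1.30 ± 0.24. Of 23 lipopolysaccharide genes 7 rose (6 adjusted over the list alone), with lpxK at 1.74 ± 0.22. Of 13 methionine genes 8 fell, with metQ at -1.11 ± 0.11. Of 16 electrophile response genes 6 fell (4 adjusted over the list alone), with hchA at -2.19 ± 0.28, and of 14 peptidoglycan genes 6 rose, with mrcA at 1.16 ± 0.26. With library totals alone 6 iron uptake and 2 peptidoglycan genes rose, 9 electrophile response genes fell, and 4 lipopolysaccharide genes rose and 2 fell. The adjusted p was 0.60, 0.61, 0.60, 0.62, 0.50, 0.50 and 0.61 with an estimated correlation, in this order, and counts adjusted over the list alone were otherwise the same. With the preset correlation the electrophile call was lost in 6 and the peptidoglycan call in 5 of 10 fits with 1 library left out, where camera gave an adjusted p of up to 0.062 (untreated replicate 1) and 0.070 (SAPYR-dark replicate 2). Both calls were also lost with the replicate block, where camera gave an adjusted p of 0.062 for each. The peptidoglycan and lipopolysaccharide means of SAPYR-dark replicate 1 stood apart, at 8.70 against 8.46 to 8.52 log2 CPM and 8.32 against 8.14 to 8.17.

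**Figure D3:**
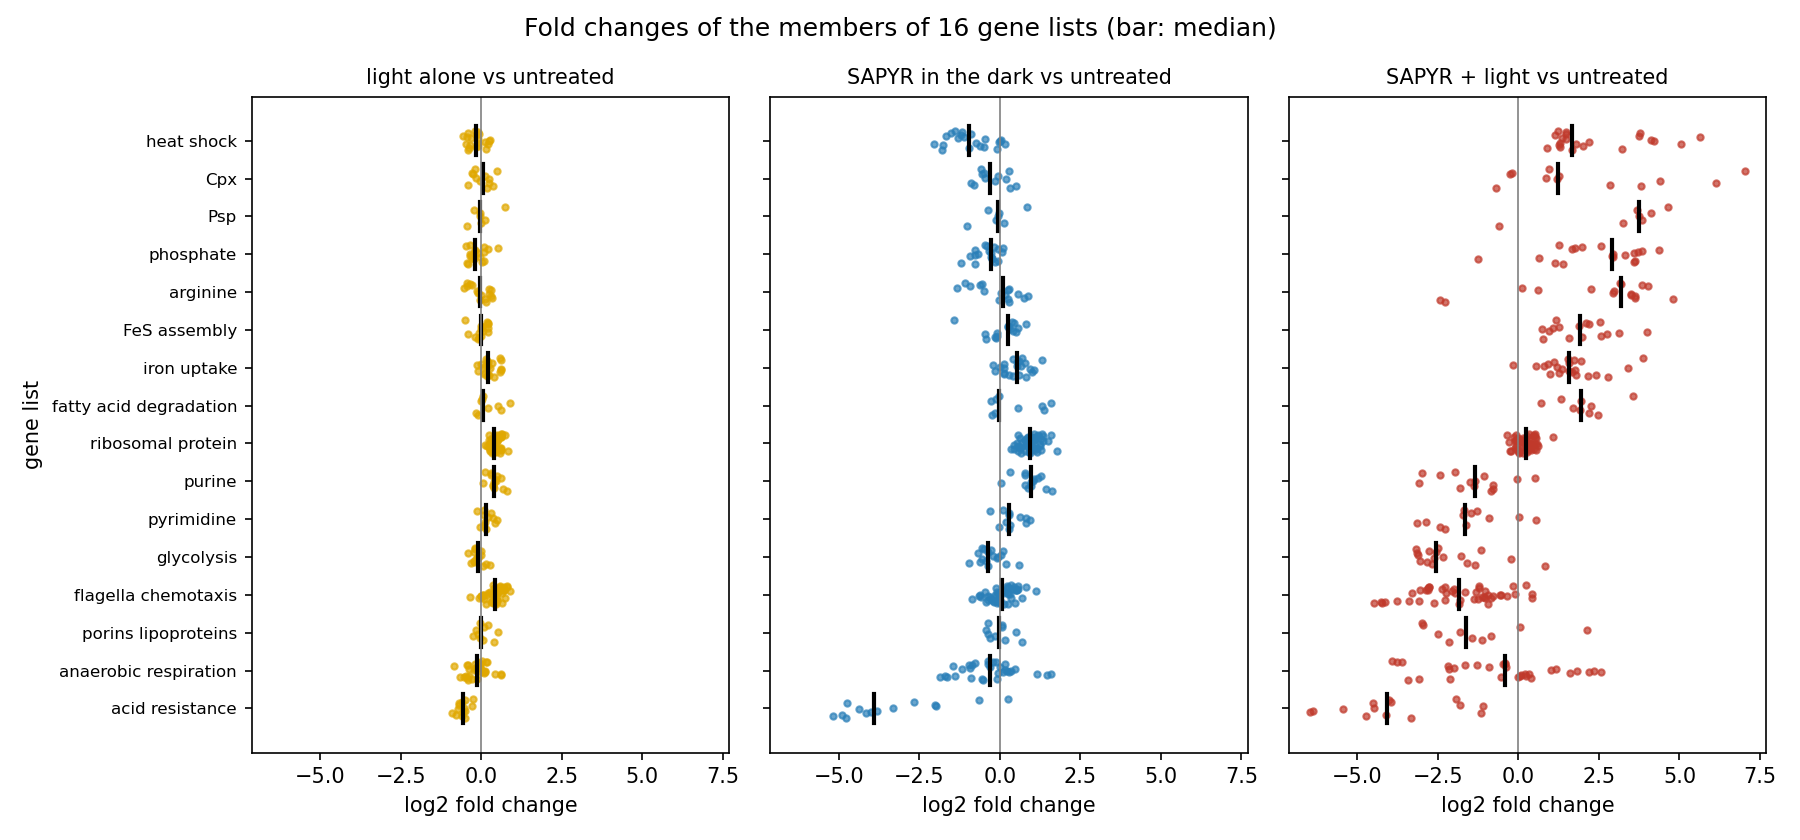
Log2 fold change against untreated cells of the tested members of 16 gene lists, with 1 point per gene and the median as a bar, for light alone, SAPYR in the dark and SAPYR with light. The heat shock median was -0.97 with SAPYR in the dark and 1.68 in photodynamic cells, and the acid resistance median was -3.91 and -4.07.

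Against light alone, photodynamic treatment raised 1456 and lowered 1121 of 3457 genes (edgeR, adjusted p under 0.05), and the leading genes were cpxP (6.52 ± 0.37), ibpB (6.10 ± 0.29), spy (5.90 ± 0.32), chaA (5.03 ± 0.23) and htpX (4.85 ± 0.17). The largest falls were hdeB (-5.89 ± 0.45), hycA (-5.89 ± 0.29), hdeA (-5.87 ± 0.40), hycB (-5.61 ± 0.24) and hydN (-5.37 ± 0.22). Camera called 27 of 48 lists, and 4 calls held with an estimated correlation at an adjusted p of 0.044 each: heat shock (21 of 21 up), arginine (13 of 16 up, 14 adjusted over the list alone), phosphate (18 of 19 up) and porins (8 of 10 down). Leaving out photodynamic replicate 5 moved hdeB to -6.58.

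Against SAPYR in the dark, photodynamic treatment raised 1505 and lowered 1168 genes, or 1721 and 830 with library totals alone. The largest rises were spy (7.03 ± 0.33), ibpB (6.75 ± 0.29), cpxP (6.73 ± 0.38), ibpA (5.41 ± 0.28) and the heat shock gene fxsA (5.29 ± 0.30), and the largest falls were hycA (-5.64 ± 0.29), hycB (-5.54 ± 0.24), hydN (-5.45 ± 0.22), hycC (-4.93 ± 0.25) and hycF (-4.91 ± 0.26). The same 4 lists held with an estimated correlation, heat shock with an adjusted p of 0.031 and arginine, phosphate and porins with 0.036. Ribosomal protein genes fell in 36 of 52 cases, 35 adjusted over the list alone, and in 44 with RLE factors and 24 with library totals alone (adjusted p = 0.68 with an estimated correlation). Of 14 acid resistance genes 2 rose, 6 fell and 6 did not pass, with a median of -0.45 (camera adjusted p = 0.33). With library totals alone 5 rose and 5 fell.

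The interaction asks whether light acted differently with SAPYR than without it, and 2511 of 3457 genes passed its test, 1409 with a positive and 1102 with a negative value, or 1635 and 753 with library totals alone (edgeR, adjusted p under 0.05). The largest positive values were ibpB (7.21 ± 0.36), spy (6.79 ± 0.40), cpxP (6.22 ± 0.45), the sulphate-binding protein gene sbp (6.18 ± 1.17, and 4.76 without untreated replicate 4) and ibpA (5.97 ± 0.36). The largest negative values were hydN (-5.52 ± 0.28), hycA (-5.38 ± 0.36), hycB (-5.33 ± 0.29), the fumarase gene fumB (-4.87 ± 0.36) and hycC (-4.83 ± 0.32). All 21 heat shock genes had a positive value past the threshold, with a median of 3.00 (camera adjusted p = 0.020 with an estimated correlation), and so had 18 of 19 phosphate genes and 13 of 16 arginine genes (adjusted p = 0.044 for both with an estimated correlation). All 14 purine genes had a negative value past the threshold, with a median of -2.87 (adjusted p = 0.20 with an estimated correlation). Of 14 acid resistance genes 4 were positive, 4 negative and 6 not called, or 4 positive and 3 negative adjusted over the list alone. Adjusted over the list alone, the phosphate genes were 18 positive and 1 negative, and the heat shock, arginine and purine counts were the same.

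Across 3457 genes, the fold changes of light with SAPYR and of light without it, which share no library, correlated at a Pearson r of -0.24 and a Spearman rho of -0.26. Without the 4 libraries that stand apart the Pearson r was -0.15. The fold changes of SAPYR under light and in the dark, which also share no library, correlated at 0.02 and -0.06. Genes are not independent replicates, so no p is given. Of the 706 genes that fell with SAPYR in the dark and the 1121 that fell with SAPYR under light, 293 fell in both, where independent lists would share 229. For rises the overlap was 174 of 654 and 1456 genes, where independent lists would share 275. In opposite directions, 224 genes rose with SAPYR in the dark and fell with SAPYR under light, where independent lists would share 212. The reverse held for 254 genes, where independent lists would share 297.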

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

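The tests of the abundance pattern, the scaling test of the SAPYR-dark difference, the test of other splits for the genes of light alone, and the settings without photodynamic libraries 2 and 5 or without 4 libraries were chosen after the result was seen. Of 344 group values tested for a library far from the other 4, 46 held one. Chance gives such a library in about 1 in 20 groups, or 17 here. The values below are listed by library, and many of the groups share genes, so they are not independent.

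Untreated replicate 4 had a TMM factor of 1.27 (others 0.940 to 1.02) and 12.8% of its counts in its 10 most abundant genes (others 16.8 to 18). Its mean log2 CPM stood apart for electrophile response genes (6.15, others 6.38 to 6.47), NADH dehydrogenase (7.78, others 8.19 to 8.33), glycolysis (10.3, others 10.8 to 11) and pyrimidine synthesis (7.95, others 8.64 to 8.89). So did its log2 CPM of hycF (8.0, others 8.81 to 9.07), hycE (9.53, others 10.6 to 10.8) and adhE (12.9, others 14.1 to 14.4). Untreated replicate 5 was at 3.78 for chaA (others 4.48 to 4.65) and 2.78 for alx (others 3.13 to 3.27). Among light-alone libraries, replicate 2 was at 8.28 for hycF (others 8.64 to 8.75) and replicate 1 at 8.24 for yjcD (others 7.02 to 7.34).

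SAPYR-dark replicate 1 stood apart in the mean log2 CPM of heat shock (8.65, others 9.02 to 9.12), ribosome hibernation (5.29, others 5.51 to 5.55), pentose phosphate (7.33, others 7.68 to 7.77), peptidoglycan (8.70, others 8.46 to 8.52), lipopolysaccharide (8.32, others 8.14 to 8.17) and anaerobic respiration genes (6.25, others 6.46 to 6.55). In the same library chaA was at 5.55 (others 4.55 to 4.83), artJ at 4.44 (others 3.53 to 3.70), lpxP at 6.11 (others 5.15 to 5.19), hycB at 8.59 (others 9.16 to 9.21), hydN at 8.89 (others 9.38 to 9.58), hycC at 9.96 (others 10.4 to 10.5), gadB, without counts there, at the floor of -2.22 (others 0.843 to 1.42) and slp at 0.730 (others 3.09 to 3.58). SAPYR-dark replicate 3 was at 6.47 for thiol redox genes (others 6.86 to 6.99), replicate 4 at 5.50 for ibpB (others 5.80 to 5.90), and replicate 5 at 6.83 for Cpx genes (others 6.87 to 6.89) and 3.93 for phosphate genes (others 3.75 to 3.80).

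Photodynamic replicate 2 stood apart in Cpx genes (9.95, others 9.03 to 9.24), Mar and efflux genes (7.84, others 6.75 to 6.99), flagellar genes (3.23, others 3.86 to 4.11) and cysteine and sulphate genes (6.15, others 8.11 to 8.36), and in alx (9.83, others 6.65 to 6.82) and nhaA (12.2, others 10.4 to 10.7). Photodynamic replicate 5 stood apart in OxyR (6.58, others 6.22 to 6.33), phage shock (8.26, others 7.53 to 7.69), histidine (7.13, others 7.61 to 7.75), peptidoglycan (7.30, others 7.80 to 7.97) and cold shock genes (7.38, others 6.59 to 6.72), and in ldrA (2.73, others 4.70 to 5.18), yjbO (8.09, others 6.40 to 6.79) and rhlE (6.67, others 7.86 to 8.09). Photodynamic replicate 4 was at 6.37 for hycE (others 5.10 to 5.46).

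The effect of light differed with and without SAPYR, by the interaction test, in 2511 of 3457 genes. Single genes with the largest values were ibpB (7.21), spy (6.79), cpxP (6.22), sbp (6.18), ibpA (5.97), hydN (-5.52), hycA (-5.38), hycB (-5.33), fumB (-4.87) and hycC (-4.83). Camera at the preset correlation called 20 lists for the interaction, with positive medians for heat shock (3.00), Cpx (1.59), Rcs and colanic acid (1.73), phage shock (3.83), iron-sulphur assembly (1.7), the citric acid cycle (1.46), arginine (2.86), histidine (1.77), branched-chain amino acids (2.16) and phosphate (3.45). The medians were negative for ribosomal proteins (-1.14), NADH dehydrogenase (-1.80), glycolysis (-2.06), flagella (-2.32), purine (-2.87), pyrimidine (-2.08), fatty acid synthesis (-1.23), peptidoglycan (-1.17), lipopolysaccharide (-0.78) and porins (-1.70). With an estimated correlation 4 of the 20 calls held: heat shock, arginine, phosphate and porins.

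Other splits of the compared libraries into groups of the same sizes were drawn 100 times per comparison. Where a group shares a culture or handling, the real split could stand out without an effect of treatment. The splits thus take the libraries as separate cultures, which the labels do not state. On that condition, chance could be excluded for the gene counts of photodynamic against untreated cells (2589, highest other split 1373) and SAPYR in the dark (1360 and 319). The same held for photodynamic against light alone (2577 and 1325) and against SAPYR in the dark (2673 and 1401). In each of these, 1 of 100 splits, the real one, reached the count. This was also so for the interaction (2511 and 1590), but its splits moved libraries across all groups. Such splits break up the separate effects of SAPYR and of light as well. They therefore do not decide whether chance gave the interaction count. For the genes of light alone the splits decide nothing, since any of the 100 reaches a real count of 0 (highest other 39). Chance could not be excluded for any count of lists from camera at the preset correlation, but the splits cannot decide this. Each group holds an odd number of libraries, so no other split of a pairwise comparison mixes the groups evenly. Every such split keeps part of any treatment difference, and camera may still call changed lists there. For photodynamic against untreated cells 21 splits reached the real 20 (highest other 29), for light alone 12 reached 15 (18), for SAPYR in the dark 42 reached 14 (19), for photodynamic against light alone 8 reached 27 (31), against SAPYR in the dark 10 reached 26 (29), and for the interaction 22 reached 20 (30). Splits that mix the groups called a median of 11 to 15 lists. What part of these calls came from the treatment difference left in the splits was not tested. The number of lists called at the preset correlation is therefore given little weight. The counts of called members within a list were not put to this test.

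In photodynamic libraries, genes of low abundance were higher and abundant genes lower than in untreated cells. A few libraries alone are argued against: the photodynamic library nearest 0, replicate 2, had a top-minus-bottom difference of -0.90, outside the range of -0.57 to 0.78 in the other 15 libraries, and replicate 5 had -3.35. An even background of reads over all genes, such as from DNA, stays open for both parts, although the protocols state a DNase step. For the low part, the gain in CPM in the fourth bin over that in the first was 2.26 (95% bootstrap interval over genes 1.52 to 3.07). An even background, taken as the same number of reads for each gene, would give like gains. A ratio of up to 1.5 was allowed for this, and the bound against it was 3. Gene length was not used in either part, so neither bears directly on reads from DNA, which grow with gene length. The interval lay above the allowance and reached past the bound. It holds the libraries fixed, so it does not measure the spread between them, and it does not decide. Median gains were 4.30 CPM in the first bin, 9.70 in the fourth, 1.29 in the fifth and -9.43 in the sixth. For the abundant part, the top 3 bins were at -0.38 against the fifth and sixth, as the mean of the 5 photodynamic libraries. The range of 2 SE over these libraries to each side was -0.64 to -0.12. Such a background would give -0.17, so a loss of abundant transcripts under treatment may contribute but was not shown.

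The SAPYR-dark difference from untreated cells was set against the main axis on which the 5 light-alone libraries differ among themselves, with 42.6% of their variance. With each library's score on it as a covariate, 85.8% of the 1360 calls were left, which argues against that axis as the whole difference. The acid resistance median was -3.91 (SD of members 1.68) before and -3.88 (SD 1.64) after, with 12 of 14 members called both times. The axis correlated at -0.18 across genes with the SAPYR-dark fold changes, so the test bears on a weak resemblance. Scaling is argued against for the acid resistance genes, whose median nearest 0 over 3 scalings was -3.91 while the median of all genes shifted by 0.20. A response to SAPYR itself is the hypothesis that the design gives, with gadA at 158 to 465 CPM in untreated libraries and 7.42 to 15.8 with SAPYR in the dark. Acid resistance, heat shock, ribosomal protein and purine genes, which led this difference, had light-alone medians of the same sign. These were -0.57, -0.16, 0.39 and 0.40, with no gene called. Both comparisons use the same untreated libraries, and what these contribute was not tested.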

How the results depend on the processing

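The settings without photodynamic libraries 2 and 5 and without 4 libraries that stand apart were chosen after the data were seen, and the other alternatives were planned. The gene counts of the comparisons with SAPYR stayed within 1.5 times under DESeq2, RLE factors, library totals alone, no low-count filter, tRNA genes removed, the block, the omission of any compared library and the setting without 4 libraries. So did the pairwise ones with only the groups compared, which was not run for the interaction, and the photodynamic ones and the interaction without photodynamic libraries 2 and 5. A 2-fold minimum gave 1658 genes for photodynamic against untreated cells, 409 for SAPYR in the dark, 1618 for photodynamic against light alone and 1693 against SAPYR in the dark, fewer by its construction.

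For light alone, edgeR called 0 genes, DESeq2 26, the setting without the 4 libraries 268, and leaving out single libraries 0 to 2; the cause was not tested. With the replicate number as a block, edgeR called 46 genes for light alone, 33 up and 13 down, where DESeq2 gave 6 up and 20 down and the setting without the 4 libraries 79 up and 189 down. It called 2632, 1419, 2620, 2731 and 2544 genes in the other comparisons, and camera with the block called 21, 13 (light alone), 12, 28, 25 and 21 lists. The numbers share no stated origin: between untreated and light-alone libraries 4 of 5 same-numbered pairs correlated over 0.1 (0.03 to 0.62, median of other numbers -0.11), and 4 of 5 untreated libraries correlated best with their own number. This was so for 3 of 5 between untreated and SAPYR-dark, 1 between untreated and photodynamic, 3 between light-alone and SAPYR-dark, 2 between light-alone and photodynamic, and 4 between SAPYR-dark and photodynamic libraries. If the numbers carried no information, about 1 of 5 libraries would match best with its own number. Only untreated with photodynamic libraries stood at that rate, and the others lay above it. The group pairs share libraries, so these counts are not independent. They point towards a shared origin of some libraries, but the labels state none, and the numbers were not taken as pairs.

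Leaving out single libraries gave 2525 to 2717 genes for photodynamic against untreated cells, 1105 to 1336 for SAPYR in the dark, 2527 to 2740 and 2603 to 2806 for photodynamic against light alone and SAPYR in the dark, and 2430 to 2675 for the interaction. Lists called ran from 19 to 22, 11 to 17 (light alone), 12 to 17, 24 to 27, 23 to 26 and 20 to 23. With an estimated correlation 0, 0 (light alone), 1, 4, 4 and 4 lists were called, and with fry 41, 0, 25, 41, 45 and 40. fry does not compare a list with other genes, and for the rest the cause was not tested. The correlation of the light effects, -0.24, was -0.26 to -0.18 without single libraries and -0.15 without the 4 libraries; the cause was not tested. Among the values of named genes, 13072 of those with a library left out stayed on their side of the threshold, 235 fell short of it, 13 passed it, and none reversed. At least 1 such call was lost for 32 genes in SAPYR in the dark and 9 in photodynamic against untreated cells. The simulations, at these depths and with 1 value of the spread per gene for all groups, recovered 34.3% of 1.5-fold changes for photodynamic against untreated cells. Which of depth and spread limits this was not tested, and the rate need not hold where most genes change.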

Other observations

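The sentences here describe lists fixed before the data were examined that were not called as lists for photodynamic against untreated cells, and the choice of which to describe was made after the result was seen. Of 16 listed fimbria and curli genes only 6 were tested. All 6 rose in photodynamic cells, with csgD, the curli regulator gene, at a log2 fold change of 2.92 ± 0.58 (SE, n = 5 per group) and csgB at 2.84 ± 0.44 (camera adjusted p = 0.098). Of 14 cold shock genes 11 rose and 1 fell, with the RNA helicase gene deaD at 2.65 ± 0.25 and cspB at 2.57 ± 0.42 (camera adjusted p = 0.073, 0.033 with the replicate block and 0.28 with an estimated correlation), and the list's mean in photodynamic replicate 5 was 7.38 log2 CPM against 6.59 to 6.72. Of 23 genes of the Rcs response and colanic acid capsule 18 rose and 3 fell, or 19 and 3 adjusted over the list alone, with wza at 2.50 ± 0.30 and osmB at 2.40 ± 0.19 (camera adjusted p = 0.072). Of 4 blue-light genes 3 rose, led by ymgB, now called ariR, at 4.54 ± 0.79 (camera adjusted p = 0.51). Without photodynamic replicate 5 these log2 fold changes were 1.86 for csgD, 2.22 for csgB, 1.92 for cspB and 3.63 for ymgB.

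Genes of respiration went both ways in photodynamic cells. Of 19 citric acid cycle genes 13 rose and 4 fell: sdhC, of succinate dehydrogenase, was at 2.69 ± 0.27, fumB, the fumarase gene used without oxygen, at -3.88 ± 0.27, and mdh at -2.41 ± 0.20 (camera adjusted p = 0.097). Of 10 terminal oxidase genes 5 rose and 2 fell, with cyoA of cytochrome bo oxidase at 2.10 ± 0.28 and appC at -3.23 ± 0.18 (camera adjusted p = 0.90). The NADH dehydrogenase gene ndh was at 2.50 ± 0.33, while 12 of the other 13 members of its list fell. Of 52 ribosomal protein genes 3 rose, or 1 adjusted over the list alone, and 49 did not pass, while 1 rose with RLE factors and 19 with library totals alone (camera adjusted p = 0.82). Among the cysteine and sulphate genes 2 rose, 1 fell and 14 did not pass (camera adjusted p = 0.85), and the list's mean in photodynamic replicate 2 was 6.15 log2 CPM against 8.11 to 8.36. Counts adjusted over the list alone were otherwise the same.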
